A study of Homo sapiens with 10 samples.

How the data were processed

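RNA was sequenced from 10 cultures of primary human lung cells carrying the surface markers CD44 and SSEA4, 5 from control lungs and 5 from lungs with idiopathic pulmonary fibrosis (IPF). Per the labels' protocols, the cells were grown in DMEM with fetal bovine serum, and RNA was extracted and made into libraries with commercial kits. Strandedness, read length, passage and sequencing batch were not given in the sources used here. Each library was labelled with a different lung, so the libraries were treated as biological replicates.

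The values the authors deposited are raw whole-number read counts per gene, with 1 column per library and no pooling. Per the submitters' processing notes, HISAT2, edgeR and the GRCh38 genome build were used. Their versions and roles, the read counter and the annotation release were not given in the sources used here. The table held 60683 gene rows, and 66 of these shared an Ensembl identifier with another row, 19 of them among the genes tested. They were kept as separate rows. Because it is not stated how reads matching several genes, or overlapping genes on opposite strands, were counted, values of near-identical or overlapping genes are uncertain.

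Total counts per library ran from 29531013 to 41945362. At this depth the spread between cultures, with a common biological coefficient of variation of 0.476, exceeded counting error for all but weakly expressed genes. The 526 sex-linked marker and Y-chromosome rows were left out as tested genes and from every figure to protect the donors. They entered only library properties, such as total counts, and the sex-linked covariate described below. Genes whose expression can follow a germline deletion or tissue type were tested but not named.

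Everything that follows was computed here from the deposited counts, with R 4.3.3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which left 15799 genes, and libraries were scaled with TMM factors. Differences between IPF and control were tested with edgeR's quasi-likelihood F test with group as the only factor, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are IPF over control, and the standard error (SE) of a log2 fold change was derived from its F statistic. Levels are CPM values scaled with TMM, given as mean ± SD over the 5 libraries of a group. Log-CPM values used a prior count of 2.

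A set of 35 gene lists was fixed before the data were examined. Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, with camera with an estimated correlation, and with fry, with adjustment over the 35 lists. The mean log-CPM of a list per library, called its score, was compared between groups with an exact two-sided permutation test over the 252 arrangements of the libraries, for which the smallest possible p is 0.00794. Principal components were computed from log-CPM of all tested genes, and the PC1 scores were compared with the same exact test. Genes were named by a rule fixed at the same point. The rule took 12 genes given whatever their result, and then, in each direction, the 10 genes with a mean of at least 1 CPM and no overlap between groups that passed the threshold with the largest fold change, filled by smallest unadjusted p where fewer passed. It added up to 4 members of smallest p from each list described. Gene positions are from GENCODE release 29 on GRCh38, in which 15721 of the 15799 tested rows had a gene.

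The alternatives tried were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and each library left out in turn. For the list tests they also included an estimated correlation, and for PC1 the 500 genes of largest variance and a prior count of 0.5. A mitosis score and a term made from the sex-linked genes were added as covariates after the data had been seen, and for the latter only counts of calls are given.

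The tests were run on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed by known folds. In the simulation of IPF against control, with 15525 genes after filtering, edgeR recovered 30% of the genes changed 2-fold, 86% of those changed 4-fold, 90% at 8-fold and 92% at 16-fold, with 5 false calls. DESeq2 recovered 48%, 94%, 100% and 96%, with 63 false calls. In a second simulation on 15799 genes, camera with the preset correlation called the 1 list moved 2-fold and 0 others. Both simulations drew genes independently, so they do not cover genes or lists that vary together between cultures. The recovered shares therefore do not bound the changes that could be missed here.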

Results

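Messenger RNA levels were measured by RNA sequencing in cultured primary human lung cells positive for CD44, a hyaluronan receptor, and SSEA4, a glycolipid found on embryonic and some adult stem cells. The labels call the cells stem-like. The 5 control and 5 IPF cultures came from different lungs. IPF is a progressive scarring disease of the lung in which fibroblasts deposit excess matrix. The libraries held 29531013 to 41945362 counts, with 34337558 ± 4692265 in control and 36225159 ± 3384419 in IPF (SD, n = 5 each, exact permutation p = 0.476). The single comparison in the design asked which mRNAs differ between control and IPF cells.

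Cultures differed widely within each group. PC1 carried 45.7% of the variance of log-CPM. IPF 1, IPF 2 and IPF 3 lay at its low end, with scores of -72.8, -78.9 and -88.5. IPF 4 had the highest score, 78.1, beside control 2, control 4 and control 5 at 59.3, 58.8 and 68.1. Control 1, control 3 and IPF 5 lay between, at -29.6, -18.2 and 23.6. The mean difference of IPF from control was -55.4 and did not pass the exact permutation test (two-sided p = 0.206, n = 5 each). Without IPF 4 it was -86.2, with exact p = 0.0476, but leaving out the highest score, in the IPF group, was bound to widen it. IPF 4 correlated with the control libraries at a mean r of 0.9553 and with the other IPF libraries at 0.8999, and IPF 5 at 0.9447 and 0.92, across genes, which are not independent replicates.

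**Figure D1:**
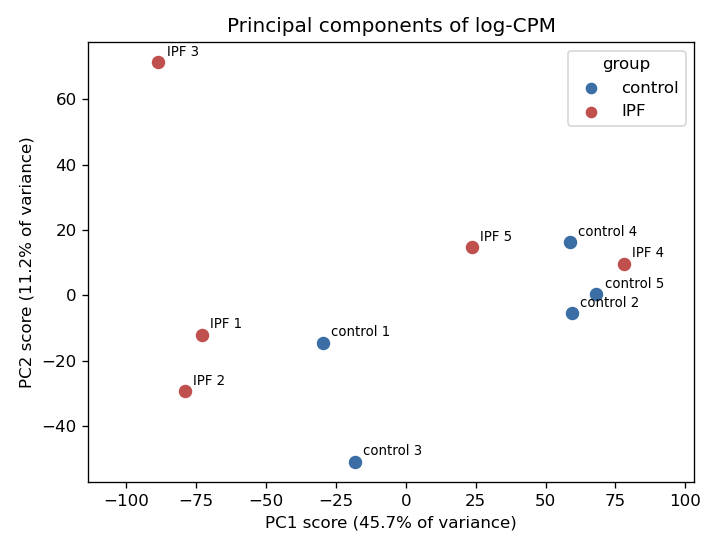
Scores of the 10 libraries on the first and second principal components of log-CPM (no unit), coloured by group, with 1 point per library. IPF 1, IPF 2 and IPF 3 sit between -88.5 and -72.8 on PC1, while IPF 4, at 78.1, sits beside control 2, control 4 and control 5.

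No single gene passed the threshold between the groups in edgeR's main fit. The genes of smallest p with every IPF library above every control library included 5 that averaged under 1 CPM in control cells. GRIA3, an AMPA-type glutamate receptor subunit, averaged 0.636 ± 0.384 CPM in control and 6.37 ± 2.56 in IPF cells, a log2 fold change of 3.32 ± 0.54 (SE). FNDC1, a secreted protein with fibronectin type III domains, averaged 0.932 ± 0.684 against 20.2 ± 17.0 CPM (log2 fold change 4.43 ± 0.76). SLIT3, a secreted guidance ligand, averaged 0.861 ± 0.603 against 14.5 ± 12.3 CPM (4.07 ± 0.85). LRRN1, a leucine-rich repeat membrane protein, averaged 0.132 ± 0.207 against 7.50 ± 7.21 CPM (5.82 ± 1.14). SLC7A5, the light chain of a large neutral amino acid transporter, lay at 68.0 ± 10.4 CPM in control and 225 ± 138 in IPF cells (1.73 ± 0.35). The other genes chosen in this direction were EPOP (1.58), IGSF8 (1.28), the creatine transporter SLC6A8 (0.94), EPDR1 (1.77) and GATD3B. GATD3B has a near-identical copy, so its count is uncertain. On GRCh38, FNDC1 spans chromosome 6 from 159169397 to 159272109, SLIT3 chromosome 5 from 168661733 to 169301129, and GRIA3 chromosome X from 123184153 to 123490915. All are protein coding.

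In the other direction, STMN3, a stathmin family regulator of microtubules on chromosome 20 from 63639705 to 63657682, averaged 58.8 ± 11.5 CPM in control and 21.4 ± 8.67 in IPF cells, with a log2 fold change of -1.45 ± 0.26 (SE, n = 5 each). INSC, an adaptor of spindle orientation, had the largest difference of this set, -2.03 ± 0.54, from 5.54 ± 3.76 to 1.36 ± 0.876 CPM. TRPV2, a cation channel, had 141 ± 31.4 CPM in control and 73.4 ± 20.8 in IPF cells (-0.94). The other 7, SLF2 (-0.63), FOCAD (-0.48), SYNRG (-0.45), WDR37 (-0.52), the phosphatase PTPN14 (-0.46), EML4 (-0.49) and CCDC32 (-0.57), had small differences.

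With edgeR's quasi-likelihood test, 0 of 15799 genes were higher and 0 lower, and the smallest adjusted p was 0.740. At an unadjusted p under 0.05 there were 769 genes with higher and 273 with lower levels in IPF, 1042 in all. Evenly spread p-values would give 790. Of 100 splits of the libraries into 5 and 5, the real one included, 22 gave at least as many genes, so no excess over chance is shown. DESeq2 called 69 higher and 11 lower, with 85 adjusted p-values not available, and limma-voom called 0. Among the DESeq2 calls were GRIA3 and FNDC1, each with a DESeq2 adjusted p of 3.9e-07. The groups did not overlap for 114 genes, 0.722% of those tested, and chance gives 0.794%. Without IPF 4 edgeR still called 0 genes, with 1514 higher and 784 lower at an unadjusted p under 0.05.

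**Figure D2:**
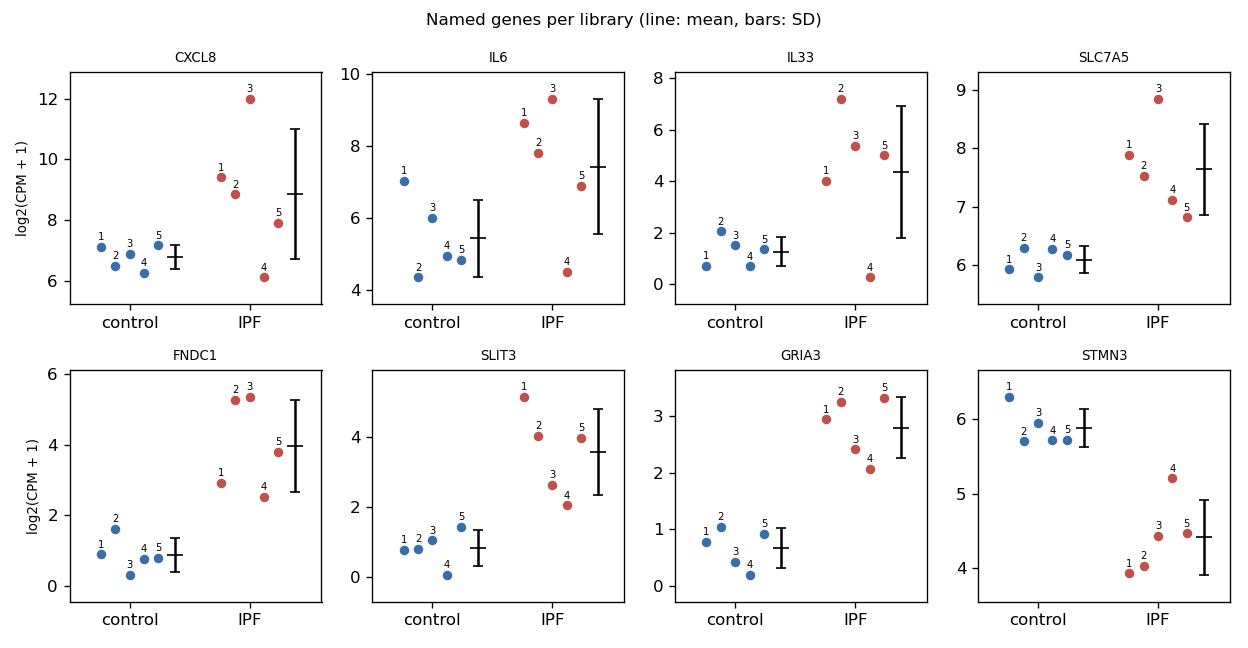
Levels of 8 genes as log2(CPM + 1) in each library, numbered by replicate, with the mean and SD (n = 5) beside each group. For GRIA3, FNDC1, SLIT3, SLC7A5 and STMN3 the groups do not overlap, whereas for CXCL8, IL6 and IL33 the level of IPF 4 lies within or below the control range.

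Inflammatory cytokine and NF-kB target genes had higher levels in IPF as a list. Of its 37 measured members, 35 had a positive fold change, the median log2 fold change was 1.71, and camera called the list (adjusted p = 3e-10). The call was lost with an estimated correlation (adjusted p = 0.737). In edgeR's test 19 members had an unadjusted p under 0.05, and 16 passed when adjusted over the list alone against 0 over all genes. DESeq2 called some members over all genes, among them IL33 (adjusted p = 0.00070) and CXCL8 (0.016). CXCL8, the neutrophil chemokine interleukin 8, lay at 114 ± 29.7 CPM in control and 1099 ± 1661 in IPF cells (log2 fold change 3.27 ± 0.92, SE), with 4042 CPM in IPF 3 and 69.1 in IPF 4. Without IPF 3 its log2 fold change was 1.66. CXCL6, a related chemokine, averaged 14.5 ± 10.5 against 265 ± 261 CPM (4.20). IL33, an alarmin cytokine, averaged 1.58 ± 1.05 against 46.1 ± 56.7 CPM (4.87 ± 1.19), and TNFAIP3, a feedback inhibitor of NF-kB, 31.6 ± 14.5 against 115 ± 56.8 CPM (1.86). IL6 lay at 54.0 ± 45.7 and 278 ± 242 CPM (2.37 ± 0.81). The mean log2 fold change of the list, 1.84, was 1.22 without IPF 3, 0.71 with 1 surrogate variable and 0.79 with the mitosis score as a covariate. The list score was 3.54 ± 0.575 in control and 4.88 ± 1.37 in IPF (exact permutation p = 0.0873, n = 5 each). IPF 4, the IPF library beside control 2, control 4 and control 5 on PC1, had the lowest inflammatory score of all.

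The senescence-associated list, which shares several secreted factors with the inflammatory list, had 25 of 31 members with higher levels and a median log2 fold change of 0.69 (camera adjusted p = 0.000221, and adjusted p = 0.737 with an estimated correlation). Of these, 10 had an unadjusted p under 0.05 in edgeR's test and 0 passed when adjusted over the list alone. DESeq2 called CXCL8 and CXCL1 over all genes (adjusted p = 0.016 and 0.026). Examples were CXCL1 (2.93), GDF15 (3.15) and IGFBP4 (2.23), an insulin-like growth factor binding protein with 942 ± 428 CPM in control and 4419 ± 4284 in IPF cells. GDF15, a stress-induced cytokine, had 2728 CPM in IPF 3 and 52.7 to 265 CPM in the other IPF libraries, and without IPF 3 its log2 fold change was 1.23. The mean log2 fold change of the list was 1.02 and 0.64 without IPF 3, and its call was lost with the surrogate variable (adjusted p = 0.138) and the mitosis covariate (0.269). The p53 target list was called with 24 of 28 members higher (median 0.27, adjusted p = 0.0248, and 0.737 as adjusted p with an estimated correlation). Apart from GDF15, its members of smallest p were TNFRSF10B (0.48), a death receptor, GADD45A (0.44) and the kinase PLK2 (1.37), which lay at 120 ± 75.6 and 310 ± 220 CPM. Its call was lost without control 2, control 5, IPF 1 or IPF 2 (adjusted p = 0.137, 0.140, 0.194 and 0.0523) and with the mitosis covariate (0.738), and its direction turned with the surrogate variable.

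Proliferation genes had lower levels in IPF as lists. All 31 measured members of the mitosis list had a negative fold change, with a median of -0.78, and 34 of the 35 DNA replication members did, with a median of -0.48. Camera called both (adjusted p = 2.5e-10 and 2.1e-07) and lost both with an estimated correlation (adjusted p = 0.737 for each). None of their members had an unadjusted p under 0.05 in edgeR's test (0 and 0 genes), and 0 passed when adjusted over either list alone. The members moved nearly as a unit between cultures, with an estimated correlation of 0.960 for mitosis and 0.900 for DNA replication. CENPE, a kinetochore motor, averaged 91.0 ± 45.2 CPM in control and 47.5 ± 30.7 in IPF (-0.94 ± 0.57, SE), CENPF 186 ± 83.0 and 102 ± 72.4 (-0.86), and RRM2, a subunit of ribonucleotide reductase, 218 ± 132 and 113 ± 122 (-0.95). IPF 3 had the lowest levels, with 7.19 CPM of CENPE and 10.4 of RRM2, while IPF 4, with 83.3 and 296 CPM, was within the control range. The log2 fold change of RRM2 was -1.71 without IPF 4 and -0.63 without control 5, and that of CENPF was -1.22 without IPF 4 and -0.57 without IPF 3. The mean log2 fold change of the mitosis list was -0.77, and it was -1.21 without IPF 4, -0.48 without IPF 3 and -0.26 with the surrogate variable, where its call was lost (adjusted p = 0.0521). That of DNA replication was -0.47, with -0.97 without IPF 4 and -0.31, -0.25, -0.27 and -0.23 without control 2, control 5, IPF 1 and IPF 3. It turned to 0.033 with the surrogate variable and, past the threshold, to 0.17 with the mitosis covariate. The mitosis score was 6.22 ± 0.773 in control and 5.02 ± 1.66 in IPF (exact permutation p = 0.183, n = 5 each).

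**Figure D3:**
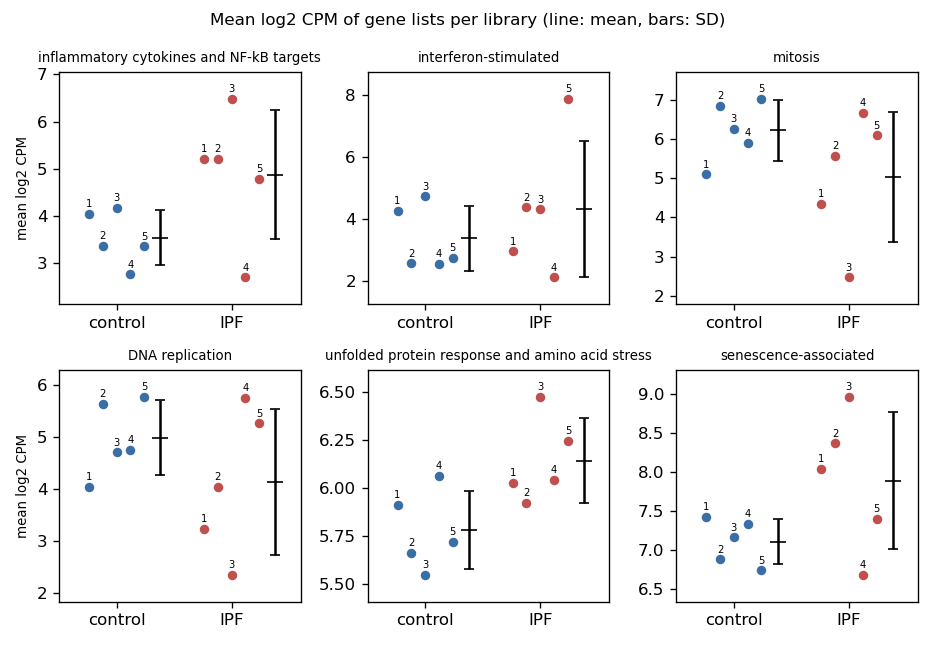
Mean log2 CPM of 6 gene lists in each library, numbered by replicate, with the mean and SD (n = 5) beside each group. IPF 3 has the highest inflammatory and the lowest mitosis score, IPF 5 stands apart for interferon-stimulated genes, and IPF 4 has the lowest inflammatory score.

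Genes of the unfolded protein response and amino acid stress differed by less than the inflammatory list, with a smaller spread of the score within each group. The scores of IPF 1, IPF 2 and IPF 4 (6.025, 5.922 and 6.043) lay below that of control 4 (6.061). Of 30 members 25 had higher levels in IPF, 6 of them at an unadjusted p under 0.05, and the median log2 fold change was 0.29 (camera adjusted p = 7.7e-06, and adjusted p = 0.737 with an estimated correlation). VLDLR, a lipoprotein receptor on this list, averaged 18.4 ± 1.56 CPM in control and 53.2 ± 36.2 in IPF (1.54 ± 0.35, SE) and was the 1 member that passed when adjusted over the list alone. Without IPF 3 its log2 fold change was 1.01. SLC3A2, the heavy chain that pairs with SLC7A5, had 83.7 ± 24.3 and 141 ± 32.0 CPM (0.75), and the stress-induced genes DDIT3 and TRIB3 had log2 fold changes of 0.82 and 0.63. The mean of the list, 0.35, was 0.23 with the mitosis covariate. The score was 5.78 ± 0.205 against 6.14 ± 0.219, with an unadjusted exact permutation p = 0.0476 (n = 5 each) and 0.602 after adjustment over the 35 lists.

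Glycolysis and hypoxia genes had higher levels for 30 of 35 members, with a median of 0.38 (camera adjusted p = 0.00109, and adjusted p = 0.737 with an estimated correlation), and their call was lost without IPF 5 (adjusted p = 0.0896). Their mean of 0.52 was 0.32 without IPF 2 and 0.33 with the surrogate variable. Examples were the kinase PDK3 (1.41), the carbonic anhydrase CA12 (1.58), ANGPTL4 (0.49) and BNIP3 (0.66). The immediate early and handling stress list had 18 of 25 members higher and a median of 0.57 (camera adjusted p = 0.0261, and adjusted p = 0.737 with an estimated correlation). IER3, an early response gene with 108 ± 21.7 CPM in control and 301 ± 142 in IPF (1.48 ± 0.33, SE), passed when adjusted over the list alone, and the transcription factor ATF3 had a log2 fold change of 1.69. This list can also follow handling of the cells, and its call was lost without IPF 5 (adjusted p = 0.170), with the surrogate variable (0.138) and with the mitosis covariate (0.0720).

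Interferon-stimulated genes had higher levels for 41 of 43 members, with a median log2 fold change of 1.97 (camera adjusted p = 0.0017, and adjusted p = 0.850 with an estimated correlation), and this rested on IPF 5. RSAD2, an antiviral enzyme, had 679 CPM there and at most 4.77 CPM in the other IPF libraries. IFI27 had 405 CPM in IPF 5 and at most 26.1 in the others, and BST2, an antiviral membrane protein, 143 against at most 21.2. Their log2 fold changes of 7.51, 4.93 and 4.63 became 1.34, 2.16 and 2.39 without IPF 5. Without IPF 5 the mean log2 fold change of the list dropped from 2.15 to 0.028 and the direction of the camera test turned (adjusted p = 0.384).

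The enzymes that crosslink and remodel matrix had higher levels for 25 of 34 members, with a median of 0.39 (camera adjusted p = 0.0261, and adjusted p = 0.737 with an estimated correlation). ADAMTS5, an aggrecanase, averaged 8.75 ± 3.14 CPM in control and 55.6 ± 60.4 in IPF (2.67 ± 0.70, SE), the prolyl hydroxylase subunit P4HA3 18.1 ± 10.1 and 119 ± 104 (2.72), and the protease inhibitor TIMP1 1190 ± 288 and 3056 ± 2802 (1.36). ADAMTS5 had 1.77 without IPF 3, TIMP1 0.69 without IPF 2, and P4HA3 -0.078 with the surrogate variable. That call was lost without control 2, control 3, control 5, IPF 2, IPF 3 or IPF 5 (adjusted p = 0.137, 0.124, 0.126, 0.1, 0.13 and 0.0732), with the surrogate variable (0.721) and with the mitosis covariate (0.968), and its mean of 0.53 was 0.35 without IPF 3. Collagens and structural matrix, with 28 of 42 members higher and a median of 0.11, did not pass (adjusted p = 0.0512). It passed without control 1, control 4, IPF 4 or IPF 5 (adjusted p = 7.7e-06, 0.018, 0.00195 and 0.0372), with DESeq2's size factors (0.0431), with library size alone (0.0209) and with the filter at 1 CPM (0.0363). Its mean log2 fold change of 0.35 became 0.96 without control 1 and 0.0092 without IPF 2. COL1A1, the main fibrillar collagen chain, varied widely within each group, at 5103 ± 5416 and 5497 ± 7283 CPM (0.11 ± 0.89). FN1, fibronectin, had a log2 fold change of -0.16 ± 0.43 and ACTA2, smooth muscle actin, -0.047 ± 0.50. The small proteoglycan BGN (1.10) and COL8A1 (1.08) had the smallest p of the list, with 0.68 for BGN without IPF 1 and 0.71 for COL8A1 without IPF 3. The contractile and myofibroblast list (9 of 22 higher, adjusted p = 0.795) and the TGF-beta response (18 of 29 higher, 0.289) did not pass, though the latter did without control 1 (adjusted p = 0.0315), where its mean log2 fold change was 0.69 in place of 0.40. Without IPF 2 that mean was 0.17. PMEPA1, a TGF-beta target, was at 6.13 ± 1.39 and 25.4 ± 21.8 CPM (2.05).

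Alveolar fibroblast markers had higher levels for 14 of 16 measured genes (median 0.62, camera adjusted p = 0.0364, and adjusted p = 0.825 with an estimated correlation). TCF21, a transcription factor of lung fibroblasts, averaged 161 ± 72.9 and 429 ± 405 CPM (1.41 ± 0.58, SE), with 0.68 without IPF 3, and the growth factor FGF7 had a log2 fold change of 1.58. Adventitial fibroblast markers had 9 of 12 higher (median 0.26, camera adjusted p = 0.0459, and adjusted p = 0.737 with an estimated correlation), among them complement C3 (2.48). The alveolar call was lost without control 2, control 5, IPF 1, IPF 2 or IPF 3 (adjusted p = 0.0976, 0.054, 0.111, 0.0618 and 0.272) and the adventitial one without control 5, IPF 2, IPF 3 or IPF 5 (0.054, 0.136, 0.0867 and 0.170). The alveolar call was also lost with the filter at 1 CPM (0.0536), and the adventitial one with the surrogate variable (0.721) and the mitosis covariate (0.650). The alveolar score was 5.62, 5.10 and 6.60 in IPF 1, IPF 2 and IPF 3, but 2.34 in IPF 4, the lowest of all libraries, and 2.88 in IPF 5, and control 1 had 5.41. The alveolar mean log2 fold change of 1.005 was 1.75 without control 1 and 0.49 without IPF 3, and it turned to -0.62 with the surrogate variable and -0.36 with the mitosis covariate. The adventitial mean of 0.99 was 2.40, 1.65 and 1.70 without control 1, control 3 and IPF 4, and 1.96 with no filter.

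Genes behind the markers that define the cells did not pass the test. CD44 lay at 1706 ± 449 CPM in control and 1369 ± 179 in IPF cells (log2 fold change -0.32 ± 0.22, SE, edgeR adjusted p = 0.781). ST3GAL2, the sialyltransferase that makes SSEA4, lay at 40.0 ± 6.26 and 39.2 ± 9.07 CPM (-0.030 ± 0.18). B3GALT5, the galactosyltransferase acting before it, was at 1.498 ± 1.38 and 0.669 ± 0.810 CPM (-1.16, with -0.52 without control 2 and -2.00 without IPF 5). The fibroblast marker S100A4 had 340 ± 179 and 339 ± 269 CPM, the mesenchymal surface protein THY1 434 ± 160 and 580 ± 232 CPM (0.42, and 0.23 without IPF 1), the hyaluronan synthase HAS2 314 ± 207 and 399 ± 445 CPM (0.34), and CD274, the checkpoint ligand PD-L1, 28.9 ± 25.0 and 24.7 ± 25.9 CPM (-0.23). The stemness and SSEA4 synthesis list had 7 of 15 members higher (adjusted p = 0.699). It held ALDH1A1 (1.74) and the intermediate filament NES (-1.07), and its median of -0.030 and mean of 0.071 differed in sign.

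Among the remaining lists, camera with the preset correlation called 0. Over all 35 lists, camera with an estimated correlation, fry and the exact permutation test called 0 after adjustment. The growth factor list (adjusted p = 0.0956) included BMP2, at 7.95 ± 4.12 and 41.5 ± 41.6 CPM (2.38, and 1.59 without IPF 3). The WNT list (0.295) had 2 members, RSPO3 (2.54) and AXIN2 (2.33), that passed when adjusted over the list alone. Oxidative stress and NRF2 targets (0.0703) included the ferritin heavy chain FTH1, at 2668 ± 777 and 6301 ± 2690 CPM (1.24). Hyaluronan genes had an adjusted p of 0.459, immune checkpoint and antigen processing 0.233, YAP and TAZ targets 0.459, HOX genes 0.681, and lung and limb positional factors 0.726. Cholesterol synthesis had 0.726, ribosomal proteins 0.707, mitochondrially encoded genes 0.874 and mesenchymal surface markers 0.726. Of the lists for other cell types, leukocyte (0.707), epithelial (0.828), endothelial (0.448), mesothelial (0.724), smooth muscle and pericyte (0.295), adipocyte and lipofibroblast (0.828) and glial and neural markers (0.699) did not pass. Some of these lists passed without 1 library. They were oxidative stress without control 4, IPF 2 or IPF 4 (adjusted p = 0.00579, 0.0454 and 0.0299), growth factors without control 4 or IPF 4 (0.018 and 0.0294), WNT without control 2 (0.0322), YAP and TAZ, towards lower levels, without control 3 (0.044), and ribosomal proteins without IPF 2 or IPF 5 (0.044 and 0.0313). CD14, a monocyte marker, was at 0.486 ± 0.359 and 3.05 ± 4.01 CPM, with its highest level in IPF 3.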

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

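Of 322 groups of 5 values examined (library properties, PC1, list scores and log2(CPM + 1) of named genes), 16 held a library whose gap to its nearest neighbour exceeded 0.71 of the group's range, and chance gives about 1 in 20. The number of such libraries does not exceed that rate. The rate holds for independent, normally distributed values, whereas many genes and scores here vary together, and many genes were chosen from these same data. The comparison is therefore only a rough guide. The weighing below used tests written before their results were seen, except the split test for the count of called genes. For both leukocyte tests the bound written in advance was met but was judged too weak to decide, so these readings depart from the written rule.

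The score of hyaluronan genes was 4.629 in control 5 and 3.988 to 4.143 in the other controls. In IPF 5 the immune checkpoint and antigen processing score was 6.378 against 4.713 to 5.129 in the other IPF libraries. Control 1 stood apart on the log2(CPM + 1) scale for LRRN1 (0.584), DDIT3 (4.499), FGF7 (7.61), the transcription factor GATA6 (3.212) and BMP6 (0.08678, the lowest). Control 2 stood apart for KDR (1.009), control 3 for ACKR3 (1.235) and control 4 for INSC (3.724). In the IPF group, IPF 3 was high for VLDLR (6.889) and SLC3A2 (7.626), and IPF 5 for RSAD2 (9.409, the others up to 2.528). IPF 4 was low for TNFAIP3 (4.904, the others from 6.826) and CA12 (4.829, the others from 7.713) and high for KRT15 (0.9411).

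The interferon score of IPF 5 exceeded that of every other library by 3.135 log2 units. Scaling of that library was argued against, since the gap was at least 3.057 with library size alone or DESeq2's size factors. The TMM factor of IPF 5 was 1.02, so a change of scaling could hardly have closed the gap and this outcome was nearly fixed in advance. Leukocytes in that culture stay open. PTPRC, LAPTM5 and TYROBP summed to 0.304 CPM there, not scaled with TMM (11 reads, exact 95% Poisson interval 0.152 to 0.544, counting error only), below the 2.1 CPM of the highest other library. That bound, set in advance, rests on genes near the floor in all 10 libraries and decides nothing. An interferon response of the cells in that 1 culture remains a candidate explanation, and its source, such as the donor, the culture or a virus, was not tested.

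IPF 4 lay beside control 2, control 4 and control 5, with r of 0.9775, 0.9678 and 0.9767 across genes. Its r with control 1 (0.9246) and control 3 (0.93) was below that with IPF 5 (0.9519). Its mitosis score was within the range of the controls. The PC1 score of IPF 4 lay just above that group's range and its inflammatory score just below. A control library with an IPF label was tested with the 200 genes of smallest p in a fit without IPF 4, of which 183 were in the full table. Of these, 9.84% placed IPF 4 nearer the IPF mean (exact binomial 95% interval 5.93% to 15.1%), against 59.1% of genes placing left-out controls nearer their own mean (55.9% to 62.3%). These genes were chosen for a difference between the other IPF libraries and the controls. IPF 4 had already been seen beside control 2, control 4 and control 5 on PC1. The share therefore restates that pattern and is no separate evidence of a wrong label. A wrong label would give such a value. So would an IPF culture whose cells resemble those of control lungs, which the design cannot separate from it. The next lowest share was that of control 1, at 37% (30.1% to 44.3%), and those of control 3 (44.5%) and IPF 5 (46.4%) had intervals that include 50%. Genes vary together and are not independent replicates, so these intervals are too narrow and do not measure the spread between libraries. The shares of single controls ran from 37% to 76.5%.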

How the results depend on the processing

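The mitosis and sex-linked covariates were chosen after the data had been seen. With edgeR, 0 genes passed in either direction with other scaling, other filters, 1 surrogate variable, either covariate and each library left out, where the smallest adjusted p was 0.0526, without IPF 4. DESeq2 called 69 higher and 11 lower. Of those 80, 27 had groups that did not overlap and 22 had over 50% of the higher group's CPM in 1 library, in 11 cases IPF 3. DESeq2 also made 63 false calls in the simulation. The cause of the difference between the tools was not tested. Limma-voom called 0, with a smallest adjusted p of 0.0943. With a replicate block, 1 gene was higher, PCSK2 (log2 fold change 4.76, adjusted p = 0.00624). The numbers were not taken to pair the samples, which came from different lungs. Same-numbered libraries correlated in their deviations at 0.275, -0.19, 0.191, 0.36 and 0.297, and 1 of 5 controls matched best its own number. The number of genes at an unadjusted p under 0.05 (769 higher, 273 lower) was 1672 and 443 with no filter, with more genes tested. This number was 329 and 452 with the surrogate variable, 305 and 211 with the mitosis covariate and 1988 and 1792 with limma-voom. With the sex-linked covariate the number was 369 and 219. It was 479 and 165 without control 5, 492 and 161 without IPF 3, 1514 and 784 without IPF 4, 172 lower without control 4, and 440 lower with the block. The cause was not tested.

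The 12 called lists became 4 with the surrogate variable, 7 with the mitosis covariate and 0 with an estimated correlation, which widens the error of lists whose genes vary together. PC1 separation ran from -86.2 to -39.7 over the fits without 1 library and passed only without IPF 4.

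Of 122 named genes under 19 other settings, 108 kept their direction throughout and 14 turned under at least 1, in 46 combinations of gene and setting, and the cause was not tested. S100A4 turned with library size alone (0.0020), the filter at 1 CPM (0.0059), the surrogate variable (0.20) and the mitosis covariate (0.17). With the block, ACTA2 (0.32), COL1A1 (-0.28), HAS2 (-0.24) and CPA4 (-0.11) turned. With the surrogate variable, COL1A1 (-0.58), CD274 (0.67), P4HA3 (-0.078), CHAF1B (0.013), CLU (-0.30), PLIN4 (-0.39) and BCHE (-0.031) did. The mitosis covariate turned CD274 (0.41), POLA1 (0.063), CHAF1B (0.081), PLIN4 (-0.71) and BCHE (-0.20). Limma-voom turned ST3GAL2 (0.084), ACTA2 (0.70), FN1 (0.38) and HAS2 (-1.22). Without 1 library the ranges were ST3GAL2 -0.15 to 0.051, S100A4 -0.30 to 0.29, ACTA2 -0.29 to 0.54, FN1 -0.38 to 0.26, COL1A1 -1.16 to 0.97, CD274 -1.02 to 0.40, HAS2 -0.27 to 0.64 and CPA4 -0.47 to 1.08.

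For lists, the direction is that of the camera test and the values are mean log2 fold changes, which can differ in sign from it. The direction turned, for untested causes, with no filter for stemness (0.43), epithelial (0.68) and endothelial markers (-0.077), and with the filter at 1 CPM for epithelial (0.11) and mitochondrial genes (0.025). With the surrogate variable it turned for collagens (-0.30), TGF-beta (-0.067), YAP and TAZ (-0.078), DNA replication (0.033), p53 (0.014), alveolar fibroblast (-0.62), positional factors (-0.21), HOX (-0.36), adipocyte (-0.26), epithelial (0.13), glial (-0.21), mitochondrial (0.045) and ribosomal genes (-0.012). With the mitosis covariate it turned for collagens (-0.067), TGF-beta (0.090), DNA replication (0.17), oxidative stress (0.022), alveolar fibroblast (-0.36), positional factors (-0.11), HOX (-0.034), adipocyte (-0.19), epithelial (0.085), glial (0.085) and ribosomal genes (-0.079), and DNA replication (adjusted p = 0.0289) and ribosomal genes (0.0196) passed in the turned direction. Calls gained with other settings were growth factors with library size alone (0.0485), oxidative stress with the filter at 1 CPM (0.0374) and cholesterol synthesis with the mitosis covariate (0.00724). Without 1 library the means ran for contractile genes from 0.065 to 0.35, stemness -0.039 to 0.38, mesenchymal 0.030 to 0.22, epithelial -0.24 to 0.40, positional factors 0.038 to 0.21, adipocyte 0.14 to 0.74, mitochondrial -0.092 to 0.16, HOX -0.26 to 0.29, ribosomal -0.035 to 0.14, cholesterol -0.10 to 0.23, leukocyte 0.26 to 0.71, interferon 0.028 to 2.59 and checkpoint genes 0.24 to 0.73.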

Other observations

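The ends of PC1, the main axis of variation, carried distinct sets of genes, listed by a loading rule chosen after the data had been seen (protein coding, at least 10 CPM on average, X chromosome left out). At the end of control 2, control 4, control 5 and IPF 4 the 10 largest loadings included OXTR, the oxytocin receptor, ESM1, PODXL and the integrin ITGA6. At the other end they included ADH1B, ADAMTS8, the prohormone convertase PCSK2, the prostacyclin synthase PTGIS, SPON1, COL14A1 and the apolipoprotein APOE. These did not mark IPF 1, IPF 2 and IPF 3 alike. ADH1B was highest in control 1, at 388 CPM against 113, 6.87 and 292 in those libraries, and IPF 2 had 0.61 CPM of PCSK2 against 7.24 in control 3.

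The tests of other groupings of the libraries were written before their results were seen, except that for the count of called genes. Over 100 of the 126 splits of the 10 libraries into 5 and 5, the real one included, all 100 gave at least the 0 called genes of the real split, which a count of 0 makes certain, so this decides nothing. For genes at an unadjusted p under 0.05, 22 gave as many as the real 1042, with 7033 as the highest and 485 as the median of the others. For lists called by camera, 44 gave as many as the real 12, with 23 as the highest and 11 as the median of the others. Chance is therefore not excluded for these last counts, and the 12 called lists are about what an arbitrary split of these cultures gives. The split that set control 1, control 3, IPF 1, IPF 2 and IPF 3 against the rest called 5090 genes where the real split called 0. These 5 libraries are those below 0 on PC1, so this count restates that axis and is no separate evidence. The difference between groups on PC1 did not pass the exact permutation test with all libraries (p = 0.206). It passed without IPF 4 (exact p = 0.0476) but in no other fit without 1 library (exact p from 0.143 to 0.397). IPF 4 had the highest PC1 score, against the direction of the group difference, so leaving it out was bound to widen that difference. That p is no evidence that the axis follows the disease label, and the question stays open. The labels used here give no batch, passage or date against which the axis could be checked. Whether control and IPF lungs were collected and cultured over the same period is not given either. A difference in time between the groups is therefore not separated from disease in any comparison here. Other traits of the donors may differ between the groups as well.

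The inflammatory list, with a score 1.33 ± 0.66 log2 units (SE) higher in IPF, was weighed against fewer dividing cells in the IPF cultures and against leukocytes. With the mitosis score as a covariate the difference was 0.591 ± 0.516, or 1.15 SE above 0, which does not decide. The mitosis and inflammatory lists lay towards opposite ends of PC1, with mean loadings (times 1000) of 16.9 and -16.56. The covariate therefore does not separate slower division of the cells from anything else that varies along PC1. For leukocytes, the bound set in advance was met, as PTPRC, LAPTM5 and TYROBP summed to 0.46 CPM (all leukocyte marker sums and the CD14 level that follow are not scaled with TMM) in IPF 3, the library with the highest inflammatory score. That bound was too narrow for a difference between groups, since it covers 1 library and genes near the floor, and leukocytes stay open. The sum was 0.381 and 0.304 CPM in IPF 1 and IPF 5, within the control range of 0.136 to 0.915, but 2.1 CPM in IPF 2. CD14 was 9.11 CPM in IPF 3, the highest of the 10 libraries, and 7 of 8 leukocyte markers had a higher IPF mean. Most of these markers were near the floor (levels not scaled with TMM). TYROBP was read in IPF 2 alone (0.115 CPM), and LAPTM5 (1.952) and LYZ (1.263) were highest there. IPF 3 had the highest FCER1G (0.63 CPM) but 0 CPM of PTPRC, TYROBP and CORO1A. The count of markers therefore decides nothing about leukocytes in the IPF cultures. A difference between IPF and control cells stays open as a hypothesis that these data do not separate from chance.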
